A study of Rattus norvegicus with 164 samples.

How the data were processed

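RNA of the prelimbic cortex of heterogeneous stock rats had been sequenced, and 1 table of expression values was used, with 38354 genes and 130 libraries. Of the 164 samples in the labels, 34 have no column in the table: 33 had no matching genotype and 1 was removed, per the labels. The remaining 130 libraries were grouped by the kind of animal identifier, 68 with a decimal number, 51 with a code beginning with E21DCD and 11 with such a code that was reassigned, per the labels. All columns were used.

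Per the submitters' processing notes, reads were quantified with kallisto 0.48 and the estimated counts summed per gene. The unit of the deposited table is log2, of the estimated count plus 1, without scaling for library size. Checked on the file, values ran from 0 to 21.9, 36.9% of them were 0, and 61.5% of the values between 0.5 and 30 on the linear scale lay within 0.01 of a whole number. The values were turned back to the linear scale, scaled to a sum of 1000000 per library, and log2 of the value plus 1 was taken. Summed counts of 15.1 to 55.95 per library, in units of 1000000, set the depth. Because the deposited unit is log2, methods for read counts were not used. The highest correlation of centred values between 2 libraries was 0.945, and no columns were identical.

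Gene positions are those of the deposited table. The labels do not name the build, but 100% of the 38272 positions that could be compared matched gene ends of the GRCr8 RefSeq table, and 38278 symbols (99.8%) were found in it. No genome sequence was used here. Genes with a mean of at least 1 over the libraries entered the tests, 15150 in all, 14632 of them on the 20 autosomes.

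The comparisons, tests, 32 gene lists and most alternatives were chosen before the data were examined. Genes were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated t with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), the decimal against the E21DCD series and the reassigned against the other E21DCD libraries. Gene lists were compared with camera of limma, with a preset correlation of 0.01 and with an estimated correlation, and by the difference in mean z-score per list with 100000 permutations of the labels, for which 1e-05 is the smallest p. Lists with under 4 tested members got no test, which left 29. Members counted "over the list alone" had p adjusted within the list. The SD of each gene was divided by a lowess trend of the SD on the mean (frac 0.3), and genes at 2 times the trend or more were counted. The mean pairwise r of the members of a list was set against 10000 random lists from 20 bins of mean level, for which 0.0001 is the smallest p. Correlations between list scores left out shared genes and used 100000 permutations, and differences in r between the series 10000. For separate levels, a mixture of 2 normal distributions of equal variance was set against 1; a gene passed where BIC fell by 10 or more, the means were at least 4 component SDs and 1 log2 unit apart, and the smaller component held at least 5% of libraries. For neighbouring genes the first 10 principal components were regressed out, and the mean r by distance was compared with that of pairs on different chromosomes, with an exact sign test over autosomes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

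Named genes followed a rule written beforehand: the 12 largest rises and 12 largest falls past the threshold with a mean of at least 3; the 20 autosomal genes with the highest SD ratio and that mean; the 20 autosomal genes with the largest separation and up to 5 on the sex chromosomes; and the 10 pairs of genes under 200 kb apart with the largest absolute r, both with a gene symbol other than a locus number and not of 1 family by the stem of the symbol. For fixed lists they were the first 4 tested members and those with the largest change in each direction. The rule was repeated without 11 libraries, and other genes named were chosen after their values were seen. Some results that fall under the rule are not reported here.

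Alternatives were median-of-ratios scaling, other filters, a pseudocount of 0.1, covariates, other limits, and subsets of libraries. Median-of-ratios scaling had factors of 0.523 to 2.12 and shifted the median gene of a library by -0.10 to 0.84. After the data were seen, the comparisons were repeated without 11 libraries whose mean of striatal genes exceeded that of glutamatergic genes, without these and decimal replicate 15, and without 18 libraries, which are the 11 and 7 at one end of the first component of the rest (score over 0.2).

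The methods were tested on simulated data with 15150 genes. Of planted differences between the series limma found 82% at 0.25 log2, 94% at 0.5 and 100% at 1, and 9 of 197 genes called were false. For the reassigned libraries it found 48% at 0.25, 94% at 0.5 and 100% at 1, and 10 of 181 were false. In these simulations for limma each gene had independent normal values, whereas real genes vary together. The false counts therefore do not carry over to the real libraries. Random splits of those called a median of 0 genes, but up to 3295 for the series and 5440 for the reassigned libraries. All 200 genes with an SD raised 3 times were found, and none of 14950 others. All 5 planted lists and 10 planted pairs were found, and none of 29 lists or 406 pairs of independent genes. With labels drawn at random 27 of 580 list scores had p under 0.05. The mixture called none of 15150 genes with 1 normal level, but 174 of 2000 with 1 skewed level (8.7%); it found 58.0% of genes with levels 4 SDs apart and 96.0% at 5 SDs, where 0.1 of the rats were high. For neighbouring genes the excess was 8e-05 without and 0.0430 with planted correlation. The samples without a column, raw reads, genotypes and the other brain regions were not analysed here.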

Results

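RNA of the prelimbic cortex, a medial prefrontal region, was measured by RNA sequencing in heterogeneous stock rats, an outbred population bred from inbred founder strains. The series design names genetic analyses of gene expression in 3 brain regions of 1 cohort as the purpose of the data. Values of 38354 genes were deposited for 130 libraries, each from a rat with its own identifier. The animal identifiers are of different kinds: 68 libraries carry a decimal number, 51 carry a code beginning with E21DCD, and 11 carry such a code that the labels describe as reassigned. These are called the decimal series, the E21DCD series and the reassigned libraries below. No treatment, sex, batch or age is given in the sources used here. In units of 1000000, summed estimated counts per library ranged from 15.1 to 55.95, with a median of 25.8. They were 29.2 ± 9.02 in the decimal series (SD, n = 68), 25.3 ± 6.04 in the E21DCD series (SD, n = 51) and 24.8 ± 2.77 in the reassigned libraries (SD, n = 11). Between 20516 and 26540 genes per library had a value above 0, and 15150 genes entered the tests.

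The libraries held transcripts of the cell types of cortical tissue. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had a level of 10.42 ± 1.46 on the log2 scale of counts per 1000000 (SD, n = 130), and Camk2a, a kinase of excitatory synapses, 11.71 ± 0.32. Of the interneuron genes, Gad1, which makes GABA, was at 7.82 ± 0.43 and Pvalb, a marker of fast-spiking cells, at 5.00 ± 0.54. Glial genes were abundant: Slc1a2, the main astrocytic glutamate transporter, was at 11.65 ± 0.30, Mbp, a structural protein of myelin, at 10.89 ± 1.07, and Csf1r, a receptor of microglia, at 6.34 ± 0.22. Endothelial Cldn5 was at 6.14 ± 0.30, mural Pdgfrb at 4.83 ± 0.26 and meningeal Col1a2 at 4.71 ± 0.79. Only 4 of 12 choroid plexus genes reached a mean of 1, with Aqp1 highest at 2.47 ± 0.80, and Rarres2 at 3.43 ± 0.44 led the 5 tested ependymal genes. Of the pituitary hormones only Pomc was tested, at 1.05 ± 0.32, and the table held no gene of the mitochondrial genome.

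In 11 libraries, all of the decimal series and none of the E21DCD series, genes of striatal projection neurons were higher than in any other library, and cortical neuron genes such as Slc17a7 and Fezf2 were lower. Drd2, a dopamine receptor of striatal neurons, ranged from 7.25 to 7.90 in the 11 libraries and from 1.94 to 4.65 in the others. Drd1 ranged from 8.08 to 8.62 against 3.09 to 5.39, the adenosine receptor gene Adora2a from 7.99 to 8.74 against 1.85 to 5.12, and the enkephalin precursor Penk from 10.10 to 10.82 against 5.32 to 7.04. Slc17a7 ranged from 2.75 to 8.83 against 9.58 to 11.20, and Fezf2, a regulator of deep-layer projection neurons, from 1.67 to 2.30 against 5.25 to 6.70. Isl1, a regulator of striatal development, lay between 2.63 and 3.35 in the 11 libraries and at 0.65 at most elsewhere. The cholinergic gene Chat lay between 3.92 and 4.59 in the 11 libraries and at 1.59 at most elsewhere. Summed counts of the 11 libraries were 18.9 to 44.98, in units of 1000000. Many of the values below are therefore also given without these 11 libraries.

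**Figure D1:**
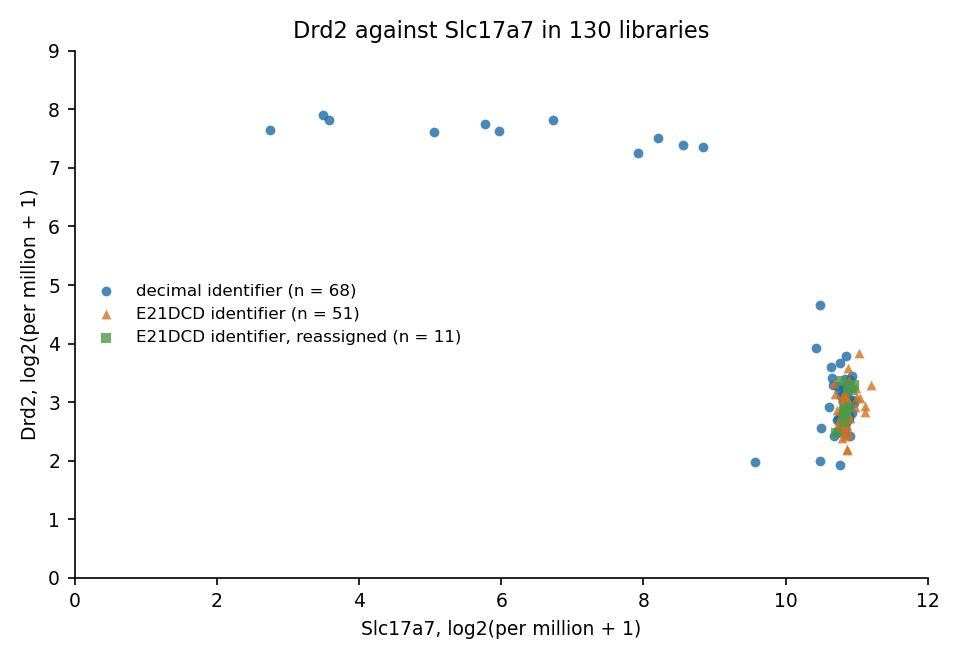
Level of Drd2 against level of Slc17a7, both as log2 of counts per 1000000 plus 1; each point is 1 of 130 libraries, coloured and shaped by the kind of identifier. In 11 libraries of the decimal series Drd2 lies between 7.25 and 7.90; in the others it lies between 1.94 and 4.65, with Slc17a7 at 9.58 or higher.

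The only label that divides the retained libraries is the kind of identifier, so the decimal series was compared with the E21DCD series; the labels state no purpose for this split. Genes of myelin were higher in the decimal series. Mobp differed by 1.07 ± 0.18 (SE; 68 libraries against 51; adjusted p = 1.27e-05), Mog by 0.93 ± 0.16 (adjusted p = 2.09e-05), Ermn by 0.93 ± 0.15 (adjusted p = 8.15e-06) and Mbp by 0.91 ± 0.18 (adjusted p = 0.000162). Genes of striatal neurons were higher as well, led by Adora2a at 1.18 ± 0.31 (adjusted p = 0.00275), with Syndig1l at 1.15, Scn4b at 1.12, Rgs9 at 1.01 and Ppp1r1b at 0.89. Lower in the decimal series were genes of cortical excitatory neurons, such as Slc17a7 at -0.85 ± 0.27 (adjusted p = 0.0126), and the activity-induced gene Btg2 at -0.89 ± 0.16 (adjusted p = 1.87e-05). The other genes with the largest rises were Rps14-ps7, Galnt6 and Mal, at 0.89 to 1.03, and those with the largest falls were Grp, Npr3, Adra1d, C1ql3, Bhlhe22, Rtn4rl2, Slc30a3, Rspo2 and Grm2, at -0.95 to -0.80.

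Once the 11 libraries were left out, the myelin genes remained higher in the decimal series: Mobp by 0.76 (adjusted p = 0.00164), Ermn by 0.67 (adjusted p = 0.00113) and Mbp by 0.61 (adjusted p = 0.0152), now in 57 libraries against 51. The ribosomal pseudogene Rps14-ps7 was higher by 1.04 (adjusted p = 0.000722). Differences of striatal and cortical neuron genes shrank, and several no longer passed: Adora2a differed by 0.25 (adjusted p = 0.0940) and Slc17a7 by -0.09 (adjusted p = 0.0651). These lost calls depended on the setting: Slc17a7 passed with median-of-ratios scaling (-0.09, adjusted p = 0.0130) and without decimal replicate 15 (-0.07, adjusted p = 0.0315). Without 18 libraries Slc17a7 did not pass (-0.05, adjusted p = 0.0729), while Adora2a did (0.29, adjusted p = 0.0177). Scn4b at 0.36 (adjusted p = 0.0217), Syndig1l at 0.34 (adjusted p = 0.0245) and Bhlhe22 at -0.28 (adjusted p = 0.00381) still passed. Among lower genes were the activity-induced Btg2 at -0.59 (adjusted p = 0.00229), Npas4, a transcription factor induced by depolarisation, at -0.51 (adjusted p = 0.0104), Dusp1 at -0.41 (adjusted p = 0.0205) and Nr4a1 at -0.36 (adjusted p = 0.0340). Lower were also Rn45s, the precursor of ribosomal RNA, at -0.85 (adjusted p = 0.00327), Nr2f2, a nuclear receptor, at -0.39 (adjusted p = 0.000177), the growth factor gene Igf2 at -0.40 (adjusted p = 0.0308) and Hpcal1, a neuronal calcium sensor, at -0.34 (adjusted p = 0.000229). The remaining named genes were Rplp2l2, Mog, Mal, Hmgb1l2, Galnt6, Bcas1 and Mag, higher by 0.54 to 0.70, and Gpc3, Glra3, Hgf and Igip, at -0.39 to -0.34. Without 18 libraries Igip did not pass (-0.20, adjusted p = 0.0586) and Hmgb1l2 went from 0.61 to 0.35.

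The gene lists fixed beforehand followed the same lines. All 14 oligodendrocyte genes rose, with a median difference of 0.83, and 13 of 14 rose without the 11 libraries, with a median of 0.53. Among oligodendrocyte precursor genes 7 of 10 rose, Olig1 by 0.41, and without the 11 libraries 3 of 10 rose. Of 14 microglial genes 9 rose, with a median of 0.15, among them Aif1 by 0.28 and Tmem119 by 0.21; 3 rose without the 11 libraries. Of 16 immediate early genes 12 fell, with a median of -0.37, and 5 fell without the 11 libraries. Of 12 meningeal fibroblast genes 11 fell, with a median of -0.48, and 5 fell without the 11 libraries, among them Igf2 and the collagen genes Col1a2 at -0.32 and Col1a1 at -0.30. Of 24 ribosomal protein genes 16 rose and 1 fell, with a median of 0.18, and 8 rose without the 11 libraries, among them Rplp1 by 0.35. Of 12 glucocorticoid-responsive genes 5 rose and 1 fell; 4 rose without the 11 libraries, among them Fkbp5 by 0.19 and Pdk4 by 0.29. Of 12 striatal genes 11 rose with all libraries and 2 without the 11, and of 10 glutamatergic genes 6 fell with all libraries and 0 without the 11 (limma; 0 adjusted over the list alone; median -0.05). Of 23 receptor genes 11 fell and 3 rose; without the 11 libraries 4 fell, among them the glutamate receptor gene Grm2 at -0.28 and the muscarinic receptor gene Chrm1 at -0.13.

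In the other lists, again without the 11 libraries, 4 members or fewer passed. Of 8 blood genes 2 rose, the haemoglobin gene Hbb-b1 by 0.35 and the haem synthesis gene Alas2 by 0.29, and of 12 astrocyte genes 2 rose, S100b by 0.18 and Gjb6 by 0.17. Of 14 genes of MHC class I, 3 rose, RT1-CE16 by 0.93, RT1-A2 by 0.36 and Psmb8 by 0.20, and Tapbp fell by 0.11. Of 20 genes of nuclear oxidative phosphorylation 2 rose, Atp5me by 0.29 and Ndufb9 by 0.17. Of 11 mural genes 2 rose and of 13 endothelial genes 1 rose. Of 10 layer 5 genes 2 fell, and 1 fell in each of the interneuron list with 13 members, the neuropeptide list with 14, the circadian clock list with 15 and the reference genes with 10. No member passed in the lists of layer 2/3 neurons, layer 6 neurons, choroid plexus, ependymal cells, heat shock, interferon response, MHC class II or sex chromosome genes, whose median differences lay between -0.03 and 0.11.

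**Figure D2:**
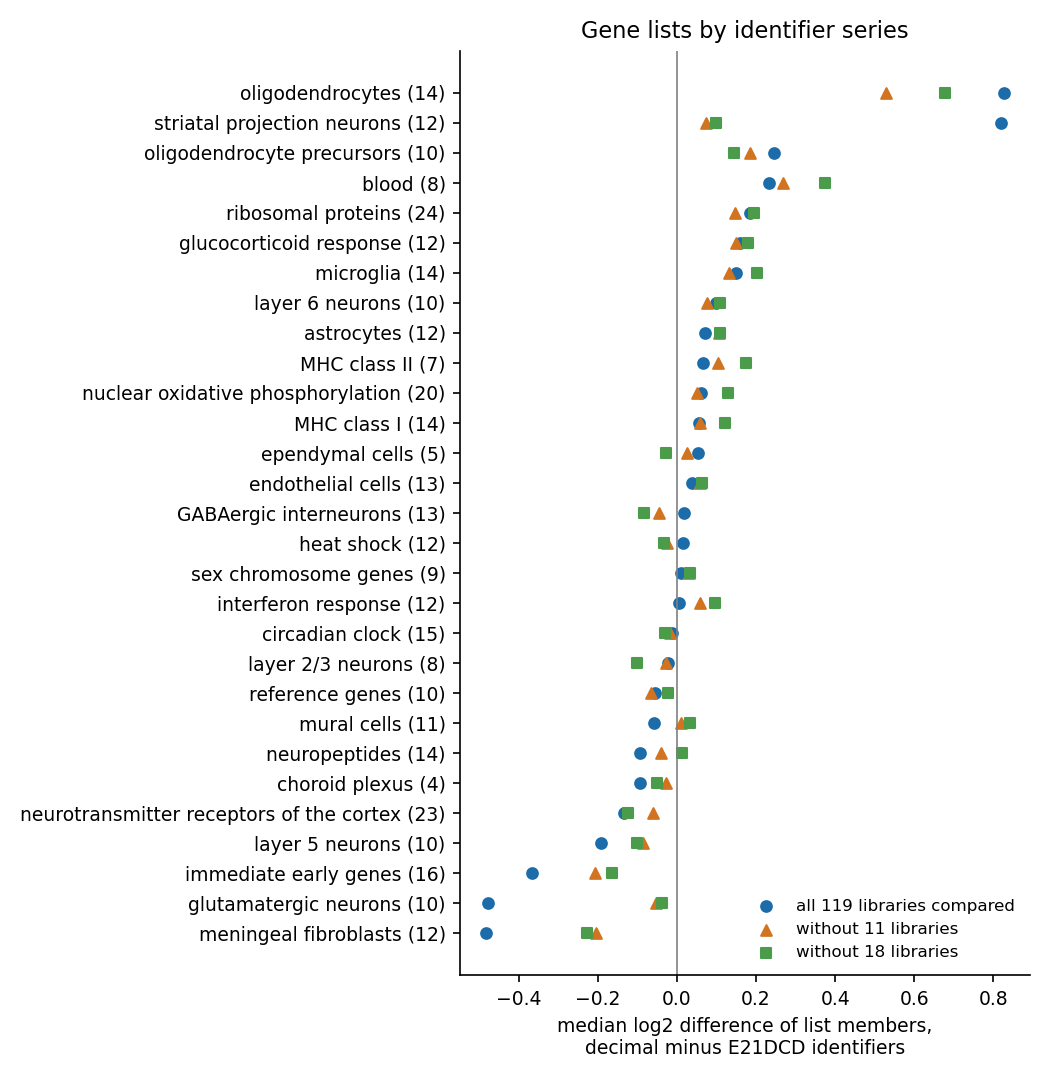
Median log2 difference of the members of each gene list, decimal minus E21DCD series, with the number of tested members in brackets; circles are the 68 and 51 libraries compared, triangles leave out 11 libraries and squares leave out 18. Oligodendrocyte genes lie at 0.83, 0.53 and 0.68; striatal genes move from 0.82 to 0.07 without the 11 libraries.

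With limma, 4184 of 15150 genes differed between the series, 2282 higher and 1902 lower in the decimal series; with median-of-ratios scaling 2164 were higher and 2378 lower, so the balance of directions depended on scaling. Leaving out the 11 libraries, 1328 genes differed, 801 higher and 527 lower, and 1095 of these were called in the same direction with all libraries; with median-of-ratios scaling 865 were higher and 784 lower. Without decimal replicate 15 as well, 2263 genes differed, 1594 higher and 669 lower. Without the 18 libraries described below 5177 genes differed, 2908 higher and 2269 lower, and 1223 of the 1328 genes were among them. Camera with a preset correlation called 10 of 29 lists, 11 without the 11 libraries and 12 without 18; with an estimated correlation none was called, and the lowest adjusted p was 0.328 with all libraries and 0.470 without the 11. Adjusted over the list alone, 14 of 14 oligodendrocyte genes, 9 of 14 microglial genes, 17 of 24 ribosomal protein genes, 7 of 12 meningeal genes, 5 of 16 immediate early genes and 4 of 12 glucocorticoid-responsive genes passed without the 11 libraries. The mean list score of oligodendrocytes differed without the 11 libraries by 0.68 SD (permutation p = 0.00017, adjusted p = 0.00304 over 29 lists), that of glucocorticoid-responsive genes by 0.36 SD (permutation p = 0.00021, adjusted p = 0.00304), that of microglia by 0.45 SD (permutation p = 0.0008, adjusted p = 0.00773) and that of oligodendrocyte precursors by 0.39 SD (permutation p = 0.00274, adjusted p = 0.0199). The scores of meningeal genes differed by -0.41 SD (permutation p = 0.00699, adjusted p = 0.0405), and the difference of -0.36 SD for immediate early genes did not pass (permutation p = 0.0159, adjusted p = 0.0612). That list passed with all libraries (-0.52 SD, adjusted p = 0.00174) and without 18 (-0.35 SD, adjusted p = 0.0374). Leaving out 18 libraries, the scores of ribosomal proteins (0.85 SD, adjusted p = 5.8e-05), nuclear oxidative phosphorylation (0.58 SD, adjusted p = 5.8e-05), receptors (-0.45 SD, adjusted p = 5.8e-05), blood (0.54 SD, adjusted p = 0.00197), astrocytes (0.51 SD, adjusted p = 0.00197) and MHC class I (0.37 SD, adjusted p = 0.00197) also passed, as did, with smaller margins, MHC class II (0.38 SD, adjusted p = 0.0277), striatal neurons (0.29 SD, adjusted p = 0.0428), layer 5 neurons (-0.27 SD, adjusted p = 0.0163), glutamatergic neurons (-0.23 SD, adjusted p = 0.0207) and interneurons (-0.21 SD, adjusted p = 0.0194), and that of microglia differed by 0.71 SD (adjusted p = 5.8e-05).

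The reassigned libraries were compared with the other libraries of the E21DCD series. A comparison of group means cannot tell whether a library was assigned to the right animal. No gene differed (limma, 11 against 51 libraries, 0 of 15150 genes at an adjusted p under 0.05, 634 at an unadjusted p under 0.05). The lowest adjusted p was 0.868, shared by Ccdc174, which was higher in the reassigned libraries by 0.24 ± 0.06 (SE), Rhov by 0.23 ± 0.06 and Dnaaf2 by 0.16 ± 0.05, and by Ids, a lysosomal sulfatase, at -0.21 ± 0.06. The median absolute difference over genes was 0.05, and the largest among genes with a mean of at least 3 was 1.41. The 51 other libraries hold 6 of the 7 libraries at one end of the first component described below, and the 11 hold none. The comparison was not repeated without those 6.

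The largest axis of variation between libraries followed striatal and cortical neuron genes. The first principal component held 32.0% of the variance of 130 libraries; its correlation with the list mean was 0.94 for striatal and -0.94 for glutamatergic genes, and the second component held 20.6%. Without the 11 libraries the first component still held 32.1%, and it went with lower receptor genes (r = -0.91) and higher ribosomal protein genes (r = 0.87). At one end of it lay 7 libraries, decimal replicate 15 and E21DCD replicates 2, 4, 8, 19, 30 and 49, none of them reassigned. In these 7 libraries 949 genes were below, and 241 above, the range of the others outside the 11. The 7 were picked by their score on a component of these same genes, with a limit set after the values were seen. That many genes set them apart was thus partly built in. Below it lay Gad2, the second GABA-synthesising enzyme, at 2.37 to 4.27 against 5.14 to 6.52, the motor protein gene Kif5c at 5.47 to 7.95 against 8.18 to 9.37, the nicotinic receptor gene Chrnb2 at 1.91 to 3.84 against 4.72 to 5.77, and the cyclin gene Ccnd2 at 1.92 to 3.06 against 4.29 to 5.42. The mean of nuclear oxidative phosphorylation genes was 7.61 to 7.94 against 6.97 to 7.52, while that of oligodendrocyte genes, 5.56 to 7.56, lay within the range of the others. Summed counts of these libraries were 15.1 to 37.7, in units of 1000000. Genes above 0 numbered 20516 to 24328 against 22643 to 26540 in the others outside the 11, and 3 of the 7 lay below all others. The gene with most counts took 0.64% to 15.1% of them against 0.37% to 1.08%, and 3 of the 7 lay above all others. No measure of RNA quality was used here, so variation between rats is not told apart from a difference in quality. In decimal replicate 15, Zfp532 alone took 15.1% of the counts, and Fos was at 0.35.

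**Figure D3:**
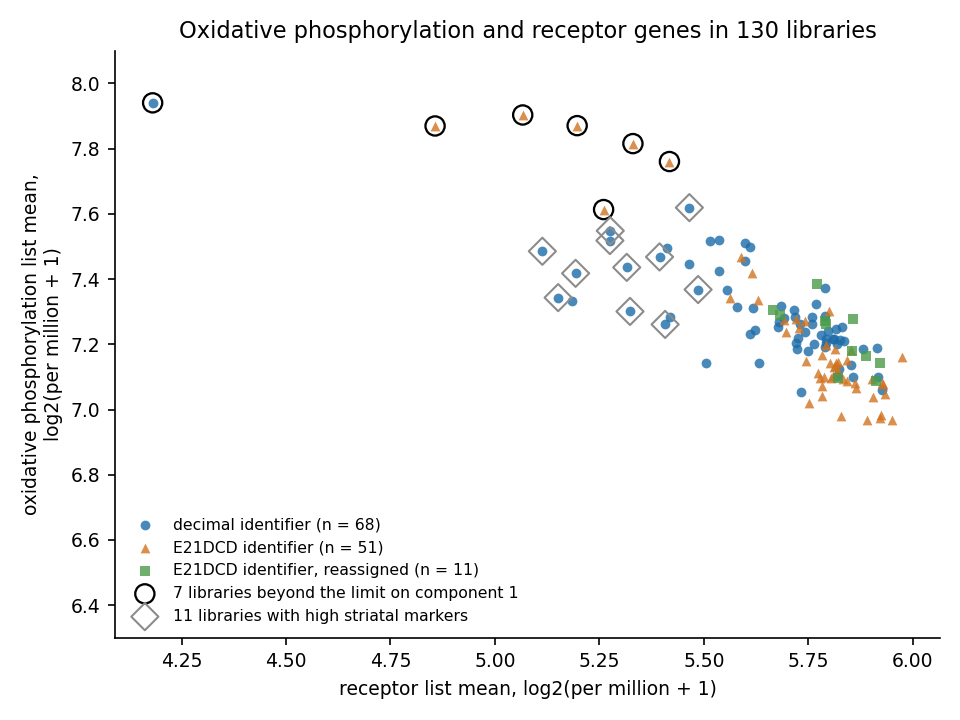
Mean level of 20 nuclear oxidative phosphorylation genes against mean level of 23 neurotransmitter receptor genes, as log2 of counts per 1000000 plus 1, in 130 libraries; circles mark the 7 libraries beyond the limit on the first component and diamonds the 11 libraries with high striatal genes. The 7 libraries lie at 7.61 to 7.94 on the vertical axis, and the others outside the diamonds at 6.97 to 7.52.

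Some genes varied far more between rats than others of the same level. Hbbl1, a beta-globin gene, had an SD of 2.03, 7.11 times the trend at its level, and ranged from 0 to 7.23. Next came genes set apart by the 11 libraries: Grp (6.23 times the trend), Npr3, Scn4b, Adora2a, Slc17a7, Adra1d, Slc30a3, Neurod6, Pdyn, Rtn4rl2, Rspo2, Syndig1l, Penk, Rtn4r, Neurod2, Rgs9 and Bdnf (5.20 times), whose ratios were 0.76 to 2.47 without those libraries. Without the 11 libraries Hbbl1 remained first at 7.80 times the trend, followed by the pseudogene Ndrg3-ps1 at 6.55, the ribosomal RNA genes Rn18s at 5.75 and Rn45s at 4.87, the zinc finger gene Zfp532 at 5.35 and Rps14-ps7 at 5.27. Rn18s and Rn45s are listed at the same position, so they may not be separate measurements. With 1 library per rat, variation between rats is not told apart from variation between libraries. Mbp at 4.38 and Mobp at 4.19, the macrophage gene Mpeg1 at 4.41, Tgfbi at 4.47 and the activity-induced Arc at 4.03 were also among the 20 highest. Adcy1 at 4.72, Gda at 4.50, Slc7a14 at 4.32, Grik3 at 4.16 and Cds2 at 4.01 fell to between 2.15 and 3.61 without 18 libraries. The other named genes were Rplp2l2, Zfp94l1, Hsp90aa1-ps17 and Rn28s. By list, all 14 oligodendrocyte genes, 11 of 16 immediate early genes and 7 of 8 blood genes reached 2 times the trend without the 11 libraries, against 0 of 14 microglial, 0 of 13 endothelial and 0 of 10 reference genes. In total 1142 of 15150 genes reached 2 times the trend, 700 without the 11 libraries, 572 of them shared. In the decimal series alone, which holds the 11 libraries, 1320 did so, and in the E21DCD series alone 972. No test was made of these counts.

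Members of several lists rose and fell together across rats. Oligodendrocyte genes were the most tightly coupled, with a mean pairwise r of 0.95, against a median of 0.10 for random lists of the same size and level. Striatal genes had a mean r of 0.94 with all libraries and 0.35 without the 11. Mean r without the 11 libraries was 0.72 for ribosomal proteins, 0.62 for meningeal fibroblasts, 0.60 for blood, 0.56 for immediate early genes, 0.56 for MHC class II, 0.48 for layer 6 neurons, 0.47 for microglia, interferon response and astrocytes, 0.45 for endothelial cells and oligodendrocyte precursors, 0.44 for nuclear oxidative phosphorylation and 0.39 for receptors. It was lower for mural cells (0.31), MHC class I (0.27), neuropeptides (0.27), choroid plexus (0.21) and the circadian clock (0.34), which also passed. Layer 2/3 neurons (0.41), layer 5 neurons (0.26), reference genes (0.26), glucocorticoid-responsive genes (0.21), glutamatergic neurons (0.15), interneurons (0.15), ependymal cells (0.14), heat shock (0.14) and sex chromosome genes (0.02) did not pass. Several of these values rested on decimal replicate 15: without it as well, mean r was 0.18 for the circadian clock, 0.11 for reference genes and 0.08 for glutamatergic neurons. Layer 2/3 neurons (0.33, adjusted p = 0.0207), layer 5 neurons (0.16, adjusted p = 0.0461) and glucocorticoid-responsive genes (0.24, adjusted p = 0.00183) then passed. The test against 10000 random lists called 17 of 29 lists with all libraries (adjusted p under 0.05), 20 without the 11 and 25 without 18.

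List means also went together across rats. Because the 11 libraries form a cluster of their own, correlations are given in the remaining libraries, 57 of the decimal series and all E21DCD libraries. Microglial and MHC class I genes rose together (r = 0.77, rho = 0.74, permutation p = 1e-05 for both, the smallest that 100000 permutations give; adjusted p = 4e-05), with r = 0.72 in the decimal series and 0.82 in the E21DCD libraries. Interferon-responsive and MHC class I genes did so too (r = 0.73, rho = 0.67, permutation p = 1e-05 for both, adjusted p = 4e-05; r = 0.70 and 0.75 within the series). Astrocyte and endothelial genes had r = 0.85 and rho = 0.73 (permutation p = 1e-05 for both, adjusted p = 4e-05; 0.86 and 0.79 within the series). Ribosomal protein genes went against receptor genes (r = -0.92, rho = -0.83, permutation p = 1e-05 for both, adjusted p = 4e-05; -0.91 and -0.92 within the series) and with nuclear oxidative phosphorylation genes (r = 0.85, rho = 0.85, permutation p = 1e-05 for both, adjusted p = 4e-05; 0.76 and 0.94 within the series). Oligodendrocytes and their precursors had r = 0.72 and rho = 0.74 (permutation p = 1e-05 for both, adjusted p = 4e-05; 0.83 and 0.46 within the series). Without the 2 libraries farthest on the x score these 6 r values were 0.75, 0.69, 0.80, -0.88, 0.84 and 0.66, and without 18 libraries 0.74, 0.71, 0.79, -0.87, 0.79 and 0.83. The circadian clock and sex chromosome genes had r = 0.81 and rho = 0.34 (permutation p = 1e-05 and 0.00022, adjusted p = 4e-05 and 0.00061; 0.88 and 0.64 within the series), but r was 0.45 without the 2 farthest libraries. Of 406 pairs computed, 272 passed with all 130 libraries, 170 positive and 102 negative; with median-of-ratios scaling 143 were positive and 133 negative, and without the 11 libraries 171 and 79. Without decimal replicate 15 as well, 147 were positive and 129 negative.

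Levels of some genes fell into separate groups of libraries, a property of interest in rats that carry few founder haplotypes per locus. Sex chromosome genes did so: Xist, the transcript that silences 1 X chromosome in females, was high without Y-linked transcripts in 63 libraries, and Y-linked genes such as Eif2s3y, Ddx3y, Kdm5d and Uty were high without Xist in 66. Both were high in 1 library, E21DCD replicate 15, with Xist at 7.61, Eif2s3y at 5.12 and Ddx3y at 5.71. On autosomes Rpl30l2 on chromosome 10, by its symbol a copy of a ribosomal protein gene, had the largest separation outside the 11 libraries: its levels were 5.57 apart without the 11 libraries, 18.2 component SDs, and 10.3 with 10 principal components also removed. It was at 0 in 63 libraries outside the 11, so its lower level lay near the floor. Values at the floor hardly vary, which can raise a separation counted in component SDs. With both steps the next genes were Rpl30 (8.57 SDs), Zfp94l1 (7.22), the heparanase-2 gene Hpse2 (6.39), Gtpbp4 (6.25), Rps10l6, Spetex2l2, Ppp2r5al1, Spetex2gl1, Tescl, Ndrg3-ps1, Fam111a (4.93), RT1-CE15, Qrfpr, Rpl36l6, Tmco5a, Zfp36, Clxn, Ccdc77 and Rbp7 (4.54). Of these Rpl30, Gtpbp4, Rpl36l6 and Rbp7 did not pass without the 11 libraries before the components were removed. Rpl36l6 and Rbp7 did not pass without 18 libraries either. Several of these genes are copies or pseudogenes by their symbols, such as Rpl30l2, Rps10l6, Spetex2l2, Rpl36l6 and Ndrg3-ps1; reads shared with related genes were not examined, so their levels are not told apart from a difference in how reads were assigned. Fam111a was high in 41.5% of the libraries and Qrfpr, a neuropeptide receptor gene, in 72.2%. Rpl30l2 was high in 15.1% and Rpl30 in 85.7%, and whether the same libraries set both apart was not examined. In simulations the criteria also passed 8.7% of genes with 1 skewed level, so a gene that passes need not have separate levels.

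**Figure D4:**
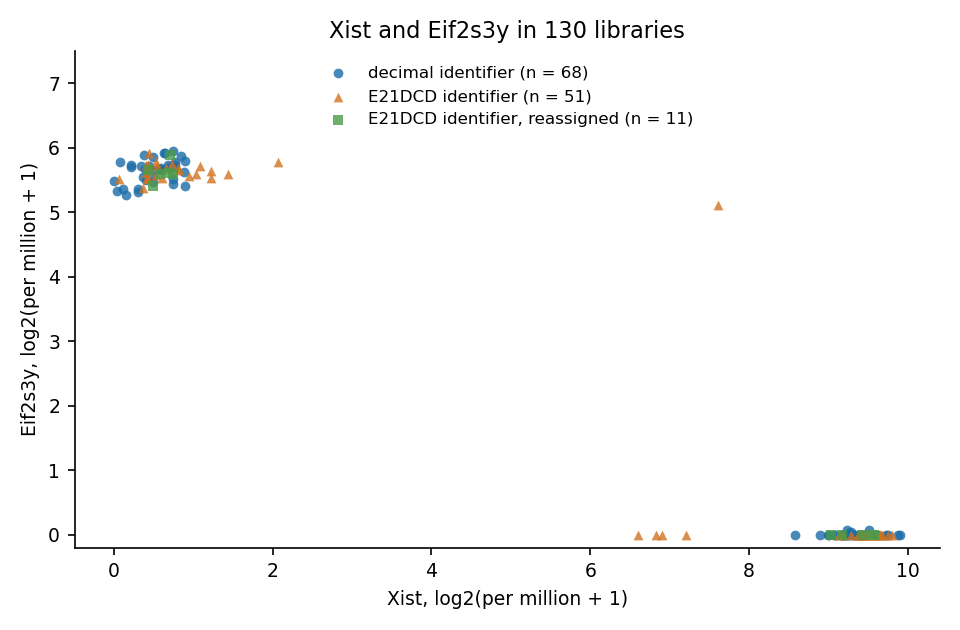
Level of Eif2s3y against level of Xist, as log2 of counts per 1000000 plus 1; each point is 1 of 130 libraries. A single library of the E21DCD series, with Xist at 7.61 and Eif2s3y at 5.12, holds both transcripts.

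With all libraries 1631 autosomal genes passed the criteria for separate levels, led by genes set apart by the 11 libraries: Pcp4l1 at 19.0 SDs, Fezf2 at 18.5, Slc32a1 at 17.6, and Pde1b, Adra1d, Lingo3, Gng7, Grp, C1ql3, Stx1a, Rarb, Penk, Dkk3, Nexn, Gnal, Fam81a, Tp53i11, Rasgrp2 and Pde7b, none of which passed without those libraries. Without the 11 libraries 710 passed, 490 of them with all libraries too. Of the 710, 493 genes had at least 6 of the 7 libraries named above among at most 10 libraries in the smaller group. Values of the same genes had picked the 7, so this count was partly built in. After Rpl30l2 the ranking ran Mtcl3 (11.4 SDs), Letm1, Ccnd2, Kif5c, Dcbld2, Rab11fip2, Dzank1, Hspa13, Megf9, Mtmr9, Hyal1, Exoc8, Mgat3, Lhfpl4, Phlpp2, Chrnb2, Xylt1, Gad2 and Agps (9.42 SDs). Without 18 libraries 112 passed, 90 of them among the 710. With 10 components removed 56 passed with all libraries and 53 without the 11, of which 47 were among the 710.

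Neighbouring genes were more alike across rats than genes on different chromosomes. After removal of 10 principal components, pairs under 10 kb apart had a mean r higher by 0.0494 ± 0.0210 (SD over 20 autosomes), positive on 20 of 20 autosomes (exact two-sided sign test p = 1.91e-06, adjusted p = 3.81e-06 over 6 distances). The excess was 0.0315 ± 0.0136 at 50 to 200 kb (20 of 20, exact p = 1.91e-06) and 0.00940 ± 0.00767 at 1 to 5 Mb (18 of 20, exact p = 0.000402), and at 5 to 20 Mb it was not told from 0 (9 of 20, exact p = 0.824). At this last distance the sign test passed with median-of-ratios scaling (15 of 20, exact p = 0.0414) and without 18 libraries (15 of 20, exact p = 0.0414). With no components removed the excess under 10 kb was 0.109 ± 0.0404, and at 1 to 5 Mb it did not pass (13 of 20, exact p = 0.263). Without the 11 libraries it was 0.0368 ± 0.0216 under 10 kb (18 of 20, exact p = 0.000402). The size of the excess depended on the setting: at 50 to 200 kb it was 0.0153 without 18 libraries and 0.0135 with 20 components removed, and at 1 to 5 Mb 0.00270 and 0.00221. Among pairs of named genes of different families, those with the largest r, chosen by size, were on chromosome 1 Zfp94l1 and Tescl (r = 0.92, 20.8 kb apart), Prss23 and the malic enzyme gene Me3 (0.84), Pira2 and Rps9 (0.83) and Fuz and Prmt1 (0.81). On other chromosomes they were RT1-A3 and Vps52 (0.84), Golm2 and Ctdspl2 (0.80), and, with opposite signs, Pip5kl1 and the adenylate kinase gene Ak1 (-0.82) and Cep131 and Slc38a10 (-0.78). These r values are those after removal of 10 components. With no components removed the pairs on chromosome 1 had r = 0.88, 0.56, 0.51 and 0.72, in the order given. RT1-A3 and Vps52 then had r = 0.58 and Golm2 and Ctdspl2 0.85. The pairs with opposite signs were at -0.46 and -0.41. Cers1 and Gdf1, listed at the same position, had r = 1.0 and the same mean, 5.85, so they were not separate measurements. Within the decimal series and within all E21DCD libraries the r of Zfp94l1 and Tescl was 0.91 and 0.95. In total 226 pairs under 200 kb had an absolute r of 0.6 or more, 167 positive and 59 negative, and 20 of them were under 10 kb apart. This count includes Cers1 and Gdf1 and pairs of 1 family, and other pairs not measured separately were not taken out.

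**Figure D5:**
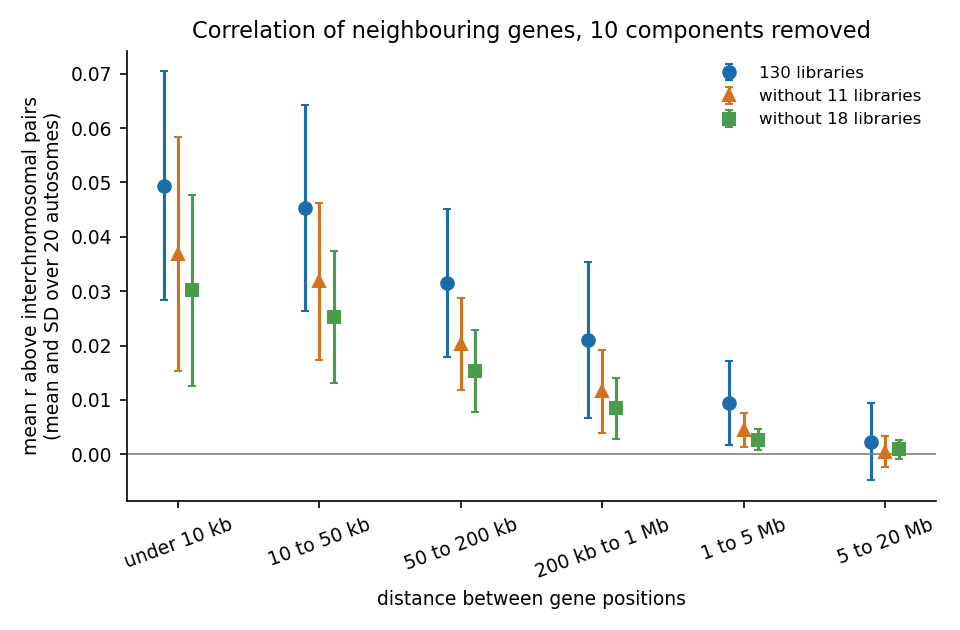
Mean r of gene pairs above that of pairs on different chromosomes, by distance between the gene positions, after removal of 10 principal components; points are means and bars SDs over 20 autosomes, for 130 libraries and without 11 or 18 libraries. The excess under 10 kb is 0.0494 for 130 libraries and 0.0301 without 18.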

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

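The test of RNA from 2 animals and the tests with the oligodendrocyte and library-total covariates were set up before their results were seen; the other tests in this part were chosen only after the result was seen. A difference between the series drew attention to the lists of oligodendrocytes and endothelial cells. Their means had r = 0.72 in the 57 decimal libraries left without the 11, and 0.16 in all E21DCD libraries, the reassigned included. The difference was 0.559 (permutation p = 0.0009, adjusted p = 0.0261 over 406 pairs). Of the 406 pairs, 26 differed in this way and 14 did so without 18 libraries; this pair was the only 1 in both, with a difference of 0.63 (adjusted p = 0.0446) without the 18.

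In the 11 libraries high in Drd2, the mean of the tested cholinergic genes Chat, Slc5a7 and Slc18a3 was above the highest of all other libraries in 11 of 11. Striatum contains cholinergic interneurons, so tissue of another brain region with striatal neurons may account for these libraries. Slc17a7 reached at most 25.0% of the median of the others, but it is among the glutamatergic genes that singled out these libraries. Its low level was thus partly built in, and decimal replicate 15, not among the 11, was also at only 41.8%. Fezf2 and Cux2 were not used for that choice. They lay at 2.30 and 5.49 at most, against medians of 6.07 and 7.29 in the others. On these genes, cortical RNA as the larger part of each library was set aside. Scaling to the library total, which moves all genes of a library the same way, was set aside: in 11 of 11 the cholinergic genes were above the highest and the cortical layer genes Cux2 and Fezf2 below the lowest of the others, none of them used to single out the libraries. Whether this arose at dissection or in the handling of samples was not tested, nor was any biological explanation.

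In the library with Xist and Y-linked transcripts, Xist was at 29.4% of the median of libraries with Xist alone, and the Y-linked genes at 71.3% of theirs on average. An XXY animal is left open by the 29.4%, because 4 libraries with Xist alone had less Xist, 3 of them among the 7 libraries at one end of the first component; against it, Eif2s3y at 5.12 was below the lowest library with Y-linked transcripts alone, 5.27. RNA of 2 animals of different sex could give such a pair of values, which sum to 101%. The library lay between the levels at 8 of 710 autosomal genes with separate levels, against a median of 2, and 85 libraries had fewer. This count cannot decide the question, because at 493 of the 710 genes the smaller group was mainly the 7 libraries at one end of the first component. RNA of 2 animals thus stays open. At the 47 of the 710 genes that passed with 10 components removed the library lay between the levels at 3, against a median of 0, and 108 libraries had fewer.

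Without the 11 libraries the number of genes that differed between the series was 31.7% of that with all libraries, and 1095 genes were called both times, so those libraries do not account for all of it. A difference in oligodendrocyte content could be part of the rest: with the mean of the oligodendrocyte list as covariate, 34.0% of the genes called without the 11 libraries were still called, which leaves this open. With this covariate 851 genes were called in all, and only 451 of them were among the 1328. Of the 851, 314 were higher and 537 lower, against 801 and 527 without the covariate. With the library total as covariate 77.6% were still called, so library total was set aside. Among 100 splits of the same sizes, the real one included, 1 reached 4184 genes and the highest other gave 3295; without the 11 libraries 2 reached 1328 and the highest other gave 2679. Chance alone was thus excluded only as far as 100 splits go, and splits that call so many genes point to a structure of the samples; no biological explanation was tested.

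For the reassigned libraries the real count was 0, which all 100 splits reach by definition, so the splits decide nothing about chance; the highest other split called 5440 genes, which points to a structure of the samples whose cause was not tested.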

How the results depend on the processing

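Scaling, pseudocount and a stricter filter left every count within 1.5 times the main one, but median-of-ratios scaling turned the series balance to 2164 higher and 2378 lower. Over the settings 402 differences of named genes kept their direction and call, 84 kept the direction but lost the call, and 8 reversed. Size was not weighed: without the 11 libraries Scn4b counts as kept, though it went from 1.125 to 0.359. The genes were named because they passed, and the stricter filter repeats part of the naming rule. Many of the kept calls were thus built in. Genes differing between the series, 4184 in the main setting, numbered 1122 with the first component as covariate, 1328 without 11 libraries, and 2263 without decimal replicate 15 as well. Without the 11 libraries they numbered 1649 with median-of-ratios scaling, 851 with the oligodendrocyte covariate and 1166 with the library total. With the first component as covariate Npr3 (0.0565), Slc17a7 (0.0540), Slc30a3 (0.0326) and Rspo2 (0.0750) reversed, as did the glutamatergic (0.0441) and striatal lists (-0.0232). Over 130 libraries that component had r = -0.94 with the glutamatergic and 0.94 with the striatal list. The covariate therefore takes up their difference largely by construction, and the reversals are not a separate result. With the oligodendrocyte covariate, which holds that list itself, the oligodendrocyte list reversed to -0.0047 and Mbp to -0.0542 and Mag to -0.0237 by construction; Ppp1r1b (-0.0223), Rspo2 (0.00465) and the striatal list (-1.5e-05) also reversed, and the cause was not tested. No list, 0 of 29, was called with an estimated correlation. Without a filter 2 genes differed in the reassigned libraries and 2746 were more variable than the trend, since more genes were tested. Variable genes numbered 733 with the median absolute deviation, 700 without 11 libraries and 2567 at a ratio of 1.5. Genes with separate levels numbered 56 with 10 components removed, 710 without 11 libraries, 53 with both, 475 without 11 libraries and decimal replicate 15, and 112 without 18 libraries. For named genes the call of separate levels changed 100 times over the settings and stayed the same 89 times. The first component held 27.1% without the 11 libraries and decimal replicate 15, and 16.8% without 18; the cause of these changes was not tested. Depth limits genes with a mean under 1, which were not tested.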

Other observations

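The tests of this part were chosen only after the results were seen. Genes of the 7 libraries at one end of the first component differed in kind. The mean of ribosomal protein genes was 7.57 to 8.74 in the 7 libraries and 6.85 to 7.95 in the others outside the 11, and 3 of the 7 lay above all others. The mean of receptor genes was 4.18 to 5.42 against 5.19 to 5.98, and 3 lay below all others; that of layer 2/3 neuron genes was 5.02 to 5.80 against 5.74 to 6.68, with 6 below. Mtcl3 was at 2.45 to 3.42 against 5.00 to 6.19. The 7 libraries lay in the smaller component at 592 to 641 of 710 genes with separate levels, and the next library at 211. Values of these same genes had picked the 7, so the ranges and counts describe them and are not separate support.

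Decimal replicate 15 had the lowest Slc17a7 outside the 11 libraries, 9.58, and the lowest Actb, 6.88. In the 11 libraries Mbp was at 12.36 to 13.49, Gad1 at 8.81 to 9.20 and Tbr1, a regulator of cortical projection neurons, at 1.40 to 5.48.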
